A study of Rattus norvegicus with 8 samples.

How the data were processed

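Retinas of male Brown Norway rats, 8 weeks old, were taken 4 h after transcorneal electrical stimulation (TES), a current passed through the eye by an electrode on the cornea, or after a sham procedure. Per the labels, 4 TES and 4 sham samples were each hybridised to 1 Affymetrix Rat Gene 1.0 ST array, a 1-colour array whose probe sets lie along the exons of each gene. The labels and the series text differ on the RNA kit's maker and on whether 1 or 2 amplification cycles were used, so neither is stated here. The samples carry the replicate numbers 1 to 4 in each group. The series text speaks of animals and replicates without tying each array to its own animal, so p-values measure only the spread between these samples, which may be technical in part.

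The deposited values are log2 GC-RMA signals, made by the authors in GeneSpring GX per the series text. GC-RMA corrects each probe for background by its base composition and summarises the probes of a probe set on a log scale. Whether and how the arrays were normalized to each other is not given in the sources used here, and their medians and SDs are close but not equal. The submitters' processing notes also name GCRMA, with no version. The base of the logarithm is not given in the sources used here and was taken from the values. They run from 0.549 to 13.2, and the highest value corresponds to 9629 on a linear scale in base 2 but to 558550 as a natural logarithm, above the 65535 that a 16-bit scanner can record. Scanner files were not analysed here, so the signal of each probe over its own background is not known. The number of arrays limits the precision.

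The value table holds 213067 probe sets with no missing value. The array's annotation, which gives old symbols, names exactly 1 gene for 172924 of them (81.2%), several for 1661 and none for 38482. Probe sets with 1 gene were averaged per array on the log2 scale, which gave 16633 genes. A gene rests on a median of 8 probe sets and at most 167, and 1788 genes rest on 1. Of the symbols, 12878 (77.4%) are current symbols in the RefSeq gene table of the assembly GRCr8. That table served only for names. No coordinates are printed, because the genome build behind the array annotation is not given in the sources used here. Glul, which the rule for named genes lists, had no probe set with that symbol and is not analysed here.

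TES was compared with sham in limma (lmFit and eBayes) with no covariate and no filter on low values, and p-values were adjusted by the Benjamini-Hochberg method over all genes. The threshold was an adjusted p of 0.05. The series text selects transcripts by SAM (Significance Analysis of Microarrays) at an unadjusted p under 0.05 and a change of at least 1.2 fold. The same 2 thresholds were applied to the limma fit and are called the study's thresholds. A version of SAM was run as an alternative. It added the median standard error (0.108) to each gene's standard error. Its p-values were pooled over all genes and all 35 splits of the arrays, the real one included. Its counts need not equal those of the series. Gene lists were tested with camera at its preset correlation of 0.01, with adjustment over the 34 lists. The alternatives were camera with a correlation estimated per list, and fry. The arrays' separation by treatment was tested as the mean Euclidean distance between groups minus that within groups, with an exact one-sided permutation test over the 35 splits of the 8 arrays into 4 and 4. The series text describes principal components and clustering for the same purpose.

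The 34 lists cover retinal cell types, tissues that a dissected retina can carry along, and processes that stimulation could touch. They are rod photoreceptors, cone photoreceptors, bipolar, amacrine, horizontal and ganglion cells, Mueller glia, astrocytes, microglia, pigment epithelium, lens, corneal and other surface epithelium, vascular endothelium and mural cells, and erythrocytes. The others are immediate early genes, glutamate receptors, GABA and glycine receptors, synaptic vesicle genes, voltage-gated channels, the Bcl2 family, caspases, the TNF superfamily, neurotrophic factors, gliosis and retinal stress, heat shock, antioxidant response, hypoxia and glycolysis, cytokines and chemokines, interferon response, oxidative phosphorylation, cytosolic ribosomal proteins, cholesterol synthesis, circadian clock and extracellular matrix. Of 929 symbols on them, 103 were not matched to the annotation. The other 826 stand for 814 measured genes, since 12 share a gene with another symbol, and 37 were matched through a synonym. The lists for the Bcl2 family, the TNF superfamily, neurotrophic factors and gliosis were drawn up knowing that work on transcorneal stimulation discusses such genes, so they are not independent of the study.

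Named genes followed a rule. With fewer than 20 genes past the adjusted p, it takes all that pass, and then the genes of smallest unadjusted p among those with at least 1.2 fold difference and non-overlapping groups, up to 12 higher and 12 lower, leaving out provisional symbols and receptor families such as olfactory receptors. It also takes the 2 members of each list with the smallest unadjusted p (4 for a list past the threshold) and a fixed set of genes discussed for this treatment (Bax, Bcl2, Bdnf, Cntf, Fgf2, Igf1, Gfap, Glul, Fos, Egr1 and Tnfrsf1b, with 1 item not reported here). The groups, tests, lists, this rule and all alternatives but 1 were fixed before the data were examined. The alternatives were a replicate block, quantile normalization, centring each array on its median, 2 filters on low values, the median or the highest-mean probe set per gene, array weights, trend and robust variance, each array left out, each probe set tested alone, SAM, an equal-variance test without moderation, other fold minimums and another distance. Leaving out sham 2 and TES 4 together was added after seeing the data.

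The fits were tested on simulated data before use, with the real genes' means and limma's variances, independent noise and 200 changed genes in each of 20 simulations. For TES against sham over 16633 genes, limma called 3.8% of genes changed by 1.2 fold at the adjusted threshold, 77.8% of those changed by 1.5 fold, 99% of those changed by 2 fold and 99.8% of those changed by 3 fold. All these fold changes were present in the same fits, where strongly changed genes ease the adjusted threshold for the others. The shares therefore need not hold where few genes change. With no changed gene, a mean of 427.9 genes (390 to 459) met the study's thresholds. A shift of 0.3 log2 units in the immediate early list was found by camera in 100% of the simulations. That share holds for independent noise and a shift of every member in 1 direction, and need not carry over to the real arrays. Work was done in R 4.3.3 with limma 3.58.1, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.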

Results

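Gene expression was measured in whole rat retina 4 h after TES or sham treatment, with 4 arrays per group. Every mean below is a log2 GC-RMA signal with its SD over 4 arrays, and every difference is TES minus sham on the log2 scale. Median signals over probe sets lay between 5.32 (TES 2) and 5.41 (sham 4). Signals of any 2 arrays correlated across genes with r from 0.9896 to 0.9945, genes not being independent replicates. The 1100 olfactory receptor genes on the array give a guide to low signal, with a median of 2.31 and a 95th percentile of 3.10. Bdnf, Fgfr3, Cd14, Bcl2a1d, Tnfsf18, Rsad2, Kera, Crygc, Eraf and Slc4a1, named below, had mean signals under that percentile.

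The main question of the design was which genes differ in the retina shortly after stimulation. Egr1 and Fos, transcription factor genes that neurons switch on rapidly after activity, ranked 1 and 3 by mean increase among the 8316 genes above the median signal, and both differences lay within the spread between arrays. Egr1 stood at 11.05 ± 1.21 after TES and 9.90 ± 1.10 after sham, a difference of 1.15 (95% interval -0.16 to 2.47). Fos stood at 5.93 ± 1.03 against 5.10 ± 0.54, a difference of 0.83 (95% interval -0.12 to 1.78). Egr1 was at 11.69, 11.86 and 11.38 on TES 1, TES 3 and TES 4 but at 9.26 on TES 2, and among sham arrays it reached 11.36 on sham 4. The limma adjusted p was 0.894 for both genes. Without TES 2 the differences were 1.75 for Egr1 and 1.26 for Fos, each with an adjusted p of 0.702. Without TES 3 the difference of Fos was 0.49 (adjusted p 0.974), and that of Egr1 was 0.87 without sham 2 (adjusted p 0.915) and 0.76 without both sham 2 and TES 4 (adjusted p 0.943). The lens crystallins Cryba2 and Cryba1 held ranks 2 and 4 by mean increase, and TES 3 was the highest array for all 4 genes.

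No gene of 16633 passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.524. At an unadjusted p under 0.05, limma gave 927 genes (5.57%), where 831.7 are expected by chance. SAM gave 929 genes at that level and the unmoderated equal-variance test 906, and neither gave a gene past the adjusted threshold. In 550 genes (3.31%) the 2 groups did not overlap, a share that chance alone puts at 2.86%. The median standard error of a difference was 0.107. Simulations of this comparison over 16633 genes held 200 genes changed by 1.2 to 3 fold. In them limma called 77.8% of genes changed by 1.5 fold but 3.8% of those changed by 1.2 fold. With fewer changed genes the adjusted threshold is stricter, so these shares need not hold for the real arrays.

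**Figure D1:**
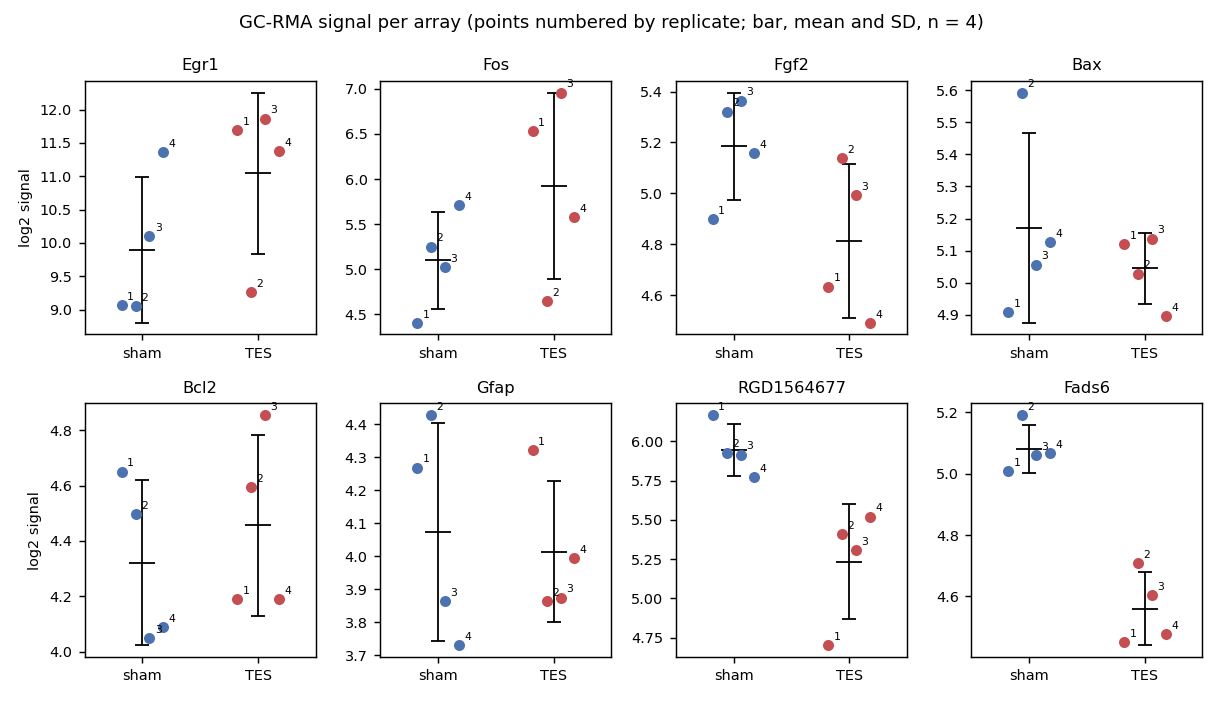
Log2 GC-RMA signal of 8 named genes on each of the 8 arrays, sham in blue and TES in red, with points numbered by replicate and bars for the mean and SD of 4 arrays. Egr1 and Fos spread widely within both groups, while the groups do not overlap for RGD1564677 and Fads6, whose adjusted p over all genes were 0.817 and 0.524.

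Of the other genes fixed for this treatment, Fgf2 differed most. Bax, which promotes apoptosis, was at 5.05 ± 0.11 after TES and 5.17 ± 0.30 after sham, a difference of -0.13 (95% interval -0.42 to 0.17). Bcl2, which opposes it, was at 4.46 ± 0.33 and 4.32 ± 0.30, a difference of 0.14 (95% interval -0.25 to 0.52). Tnfrsf1b, a TNF receptor gene, was at 3.27 ± 0.12 and 3.34 ± 0.22. The neurotrophic factors Bdnf, Cntf and Igf1 had differences of -0.07, -0.07 and -0.16, with 95% intervals that all included 0. The mean signal of Bdnf, 2.90, lay below the 95th percentile of olfactory receptors, so its small difference says little. Fgf2, a growth factor gene, was at 4.81 ± 0.30 after TES and 5.19 ± 0.21 after sham, a difference of -0.37 (95% interval -0.71 to -0.04) with an adjusted p of 0.843 in limma. Gfap, the intermediate filament of astrocytes and reactive Mueller glia, was at 4.01 ± 0.21 and 4.07 ± 0.33, a difference of -0.06 (95% interval -0.41 to 0.29). Gfap and Igf1 had the opposite sign when the median probe set stood for the gene, and Tnfrsf1b when the probe set of highest mean did.

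The genes of smallest unadjusted p with non-overlapping groups all failed the correction, with limma adjusted p between 0.524 and 0.817. The 12 higher ones differed by 0.33 to 0.60 log2 units, and 8 of them lay at or below the 95th percentile of olfactory receptors. Tmem182, a membrane protein gene, was first with 3.09 ± 0.08 after TES against 2.54 ± 0.12 after sham. Stk10, a serine/threonine kinase gene, had the highest signal of the 12 with 4.69 ± 0.05 against 4.36 ± 0.05. The C3a receptor gene C3ar1 was at 3.32 ± 0.31 against 2.72 ± 0.06. The others were Gzmc (a granzyme), Npffr2 (a neuropeptide receptor), Rnf125 (a ubiquitin ligase), Crnn, Kb21 (a keratin), Krtap14l, Hsf2bp, Prl3a1 (of the prolactin family) and Oas1h (of the oligoadenylate synthetase family). Gzmc had the opposite sign with the median probe set per gene.

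The 12 lower genes differed by -0.36 to -0.72 log2 units, and 3 of them lay at or below that percentile. Fads6, of the fatty acid desaturase family, was first with 4.56 ± 0.12 after TES against 5.08 ± 0.08 after sham. Cdh4, which encodes R-cadherin, had the highest signal with 6.87 ± 0.15 against 7.25 ± 0.10. Selplg, the P-selectin ligand gene of leukocytes, was at 5.23 ± 0.07 against 5.66 ± 0.19. Cyp27a1, a sterol hydroxylase, was at 3.35 ± 0.22 against 3.87 ± 0.15. Tmem132c, Ghsr (the ghrelin receptor), Dbil5, Tmprss9 (a serine protease), Lipt1 (a lipoyltransferase), Ntn5 (of the netrin family), P2ry14 (a receptor for UDP sugars) and Rfpl4a completed the set. Ghsr, Tmprss9, Lipt1 and Ntn5 had the opposite sign when the probe set of highest mean stood for the gene.

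The study's own thresholds, an unadjusted p under 0.05 with at least 1.2 fold, selected 597 genes (3.59%) in limma. Of these, 271 were higher and 326 lower after TES, and the groups did not overlap in 222. Genes of low signal made up most of them. The lowest quartile of mean signal held 240, the second 250, the third 91 and the highest 16, so that 82.1% lay below the median signal. SAM selected 633 genes, 596 of them among the 597. Centring each array on its median gave 609 genes, of which 72.4% were higher after TES against 45.4% in the original fit. The count was 367 without the lowest quartile (29.7% higher after TES), 129 without all genes below the median signal (23.3% higher), 348 with the unmoderated equal-variance test, 24 at 1.5 fold and 927 with no fold minimum. Only 190 of the 597 genes were selected again when the probe set of highest mean stood for the gene, and 335 with the median probe set. Testing each probe set alone gave 10921 of 213067 (5.13%). As many passed the unadjusted p alone, so the fold minimum removed no probe set. The matching count of genes is the 927 (5.57%) with no fold minimum.

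**Figure D2:**
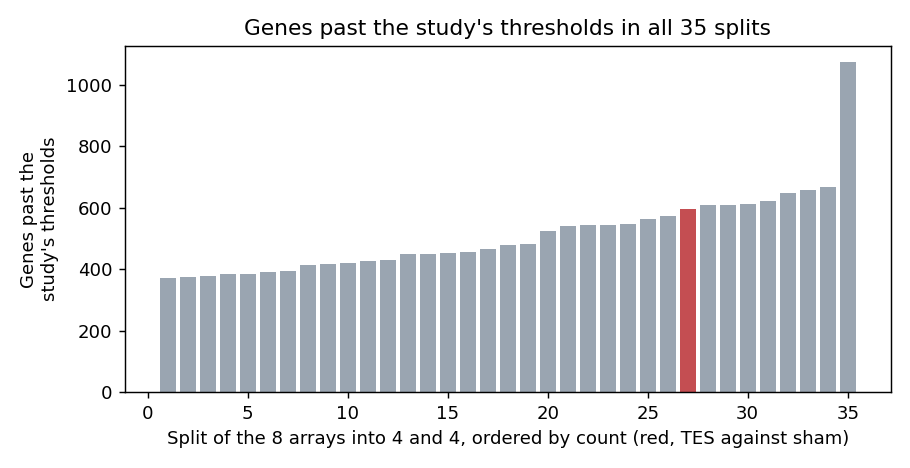
Number of genes past the study's thresholds (vertical axis) in each of the 35 splits of the 8 arrays into 4 and 4, ordered by count, with TES against sham in red. The real split gave 597 genes, 8 other splits gave more, and the highest gave 1072.

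None of the 34 gene lists passed an adjusted p of 0.05 in camera, and 5 had an unadjusted p under 0.05. The estimated correlation and both tests of fry also gave 0 lists, with a smallest adjusted p of 0.913 with an estimated correlation. Adjusted over all genes, no list member passed. Adjusted over the list alone, 1 member passed, RGD1564677 of the horizontal cell list. This came from 34 separate corrections, with no adjustment for the number of lists. Of 838 measured memberships, 51 had an unadjusted p under 0.05 in limma, where a gene on several lists counts for each. Over all genes that share was 5.57%. More members were lower than higher after TES in 23 lists, the reverse held in 9, and 2 were even. This balance depends on the scaling of the arrays: with each array centred on its median, 9 lists had more members lower and 22 more higher, and the median difference over all genes was 0.023 instead of -0.0134. In 5 lists the mean, the median and camera's direction differed in sign (astrocytes, caspases, cytokines, extracellular matrix and antioxidant response).

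Markers of retinal neurons showed no list past the threshold. Of 21 rod genes 9 were higher and 12 lower (camera adjusted p 0.884), with differences of -0.38 for Rom1, an outer segment disc protein, and 0.12 for the channel gene Cnga1. Of 13 cone genes 8 were higher (adjusted p 0.858), and Cnga3 and the short-wavelength opsin Opn1sw differed by -0.23 and -0.13. Bipolar cell genes were higher in 5 of 13 (adjusted p 0.858), with -0.15 for Pcp2 and 0.13 for Trpm1. Amacrine cell genes were higher in 6 of 17 (adjusted p 0.823), with -0.18 for Slc17a8 and -0.20 for Slc18a3. Ganglion cell genes were higher in 6 of 17 (adjusted p 0.604), with -0.49 for the transcription factor Isl2 and -0.14 for the glutamate transporter Slc17a6. Horizontal cell genes were higher in 2 of 7 (adjusted p 0.495), with -0.16 for the calcium-binding protein Calb1. The list's RGD1564677, for which RefSeq gives the symbol Onecut2, was at 5.23 ± 0.37 after TES and 5.95 ± 0.16 after sham, lower on 4 of 4 TES arrays than on any sham array. Its difference of -0.71 (95% interval -1.07 to -0.35) had a limma adjusted p of 0.00739 adjusted over the list alone and 0.817 over all genes, and it rests on 1 probe set. Rom1 and Opn1sw had the opposite sign with the median probe set per gene, and Trpm1 and Slc17a8 with the probe set of highest mean.

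Glial lists also stayed short of the threshold. Mueller glia genes were higher in 8 of 15 (camera adjusted p 0.846), with -0.18 for Hes1 and 0.11 for Gpr37. Astrocyte genes were higher in 4 of 8 (adjusted p 0.858), with 0.26 for the urea transporter Slc14a1 and -0.13 for Fgfr3. Microglia genes were higher in 9 of 21 (adjusted p 0.858), with -0.57 for Cd14, a co-receptor for lipopolysaccharide, and -0.26 for the fractalkine receptor Cx3cr1. Reactive gliosis genes were higher in 18 of 30 (adjusted p 0.823), with -0.37 for Fgf2 and -0.22 for Timp1, and this list is not independent of the study. With the probe set of highest mean, Fgfr3, Cx3cr1 and the mean of the astrocyte list had the opposite sign. Without the genes below the median signal the gliosis and cytokine lists passed in camera, with mean differences of 0.16 and -0.14. They did not pass with an estimated correlation (adjusted p 0.398 and 0.543). Egr1 is a member of the gliosis list and had its largest difference (1.15).

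None of the 5 lists tied to neuronal activity passed the threshold. More members were lower than higher after TES in all 5, but in 4 after quantile normalization and in 2 (immediate early genes and glutamate receptors) with arrays centred on their median. Immediate early genes were higher in 10 of 34 (camera adjusted p 0.604), so that Egr1 and Fos stood apart from most members. By p the list was led by Dusp5, a phosphatase of the MAP kinase pathway, with 0.27, and Per1 with -0.26. Glutamate receptor and transporter genes were higher in 5 of 29 (adjusted p 0.510), with -0.14 for Slc17a6 and 0.18 for Slc1a6. GABA and glycine receptor genes were higher in 7 of 20 (adjusted p 0.823), with -0.16 for Gabrd and -0.13 for Gabrg3. Synaptic vesicle genes were higher in 10 of 29 (adjusted p 0.858), with 0.20 for Stx1a and -0.15 for Rims1. Voltage-gated channel genes were higher in 17 of 47 (adjusted p 0.605). Among them the potassium channel Kcna4 was at 4.58 ± 0.43 after TES and 5.26 ± 0.07 after sham, and the calcium channel subunit Cacnb1 differed by -0.25. Gabrd, Gabrg3, Rims1 and the mean of the voltage-gated channel list had the opposite sign with the probe set of highest mean.

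Survival and stress lists gave small differences. Bcl2 family genes were higher in 9 of 18 (camera adjusted p 0.858), with -0.21 for Bcl2l11 and 0.18 for Bcl2a1d. TNF superfamily genes were higher in 18 of 38 (adjusted p 0.823), with -0.39 for Tnfrsf12a and 0.21 for Tnfsf18. Neurotrophic factor genes were higher in 14 of 37 (adjusted p 0.604), with -0.29 for Serpinf1, which encodes pigment epithelium-derived factor, and -0.41 for Nrtn. These 3 lists are not independent of the study. Caspase and apoptosis genes were higher in 11 of 24 (adjusted p 0.858), with -0.38 for the caspase-8 regulator Cflar and -0.20 for Casp9. Heat shock genes were higher in 13 of 29 (adjusted p 0.797), with -0.24 for Hspb1 and -0.16 for Dnajb9. Antioxidant genes were higher in 11 of 24 (adjusted p 0.858), with -0.13 for Mt1a and 0.18 for Gstm1. Hypoxia and glycolysis genes were higher in 17 of 27 (adjusted p 0.604), with 0.23 for Egln3 and -0.19 for Ddit4. Cytokine and chemokine genes were higher in 16 of 33 (adjusted p 0.858), with 0.30 for Ccl7 and -0.25 for Cxcl12. Interferon response genes were higher in 19 of 28 (adjusted p 0.604), with -0.33 for Ddx58 and 0.34 for Rsad2. The probe set of highest mean turned the sign of Hspb1, Egln3, Cxcl12 and the means of the Bcl2 family, caspase and TNF superfamily lists, and the median probe set that of the antioxidant list.

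Among lists of general cell functions, clock and ribosomal genes lay lowest. Circadian clock genes were higher in 4 of 21 and lower in 17, a mean difference of -0.09 (camera adjusted p 0.147, and 0.913 with an estimated correlation), with -0.31 for Aanat, an enzyme of melatonin synthesis, and -0.26 for Per1. Aanat had the opposite sign with either other choice of probe set (0.089 with the median one, 0.038 with that of highest mean). Without TES 1 the clock list passed at 0.0449, but not with an estimated correlation (adjusted p 0.956). Cytosolic ribosomal protein genes were higher in 14 of 65 and lower in 51, a mean difference of -0.06 (adjusted p 0.215), with 0.38 for Rpl6 and -0.37 for Rpl35a. With median-centred arrays 35 of the 65 ribosomal and 13 of the 21 clock genes were lower. Oxidative phosphorylation genes were higher in 20 of 54 (adjusted p 0.823), with -0.24 for Ndufa8 and -0.26 for Cox7b. Cholesterol synthesis genes were higher in 11 of 17 (adjusted p 0.823), with -0.25 for Pmvk and -0.16 for Lss. Extracellular matrix genes were higher in 18 of 34 (adjusted p 0.858), with -0.20 for Timp3 and 0.33 for Dcn. Ndufa8 and Lss had the opposite sign with the probe set of highest mean.

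The widest mean differences among the lists were those of lens, erythrocytes and pigment epithelium. Lens genes were higher after TES in 12 of 15, a mean difference of 0.27, and erythrocyte genes in 6 of 7, a mean difference of 0.21, each with a camera adjusted p of 0.0752 and an adjusted p of 0.913 with an estimated correlation. Mip, the lens fibre water channel, was at 3.71 ± 0.20 against 3.23 ± 0.27, and Crygc, a lens crystallin, at 2.69 ± 0.31 against 2.26 ± 0.16. Crygc is among the 7 of 15 lens genes at or below the 95th percentile of olfactory receptors. The erythrocyte genes Eraf and Slc4a1 differed by 0.26 and 0.13, but both are among the 4 of 7 erythrocyte genes at or below the 95th percentile of olfactory receptors. Pigment epithelium genes were lower in 12 of 19, a mean difference of -0.17 (adjusted p 0.123, and 0.913 with an estimated correlation). Rpe65, the isomerase of the visual cycle, was at 4.98 ± 0.41 after TES against 5.49 ± 0.22, and Rdh5, a retinol dehydrogenase, at 4.71 ± 0.40 against 5.21 ± 0.23. Endothelial and mural cell genes were higher in 4 of 14 (adjusted p 0.604), with -0.20 for Cspg4 and -0.14 for Vwf, whose sign turned with the probe set of highest mean. Corneal and surface epithelium genes were higher in 5 of 13 (adjusted p 0.858), with -0.21 for Kera and 0.33 for Dcn.

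Single arrays decided these lists. The lens list passed in camera without sham 2 (adjusted p 0.000383), without TES 1 (0.0436) and without TES 2 (0.00236), while its mean difference was 0.03 without TES 3 (adjusted p 0.904) and 0.13 without sham 3 (0.493). The erythrocyte list passed without sham 2 (0.00137), without sham 3 (0.0351) and without TES 1 (0.0436), while its mean difference was 0.13 without sham 1 (0.313) and 0.12 without sham 4 (0.527). The pigment epithelium list passed without TES 2 (2.54e-06), while its mean difference was -0.10 without TES 1 (0.834) and -0.11 without TES 4 (0.601). None of these calls held with an estimated correlation, where the smallest adjusted p was 0.434.

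**Figure D3:**
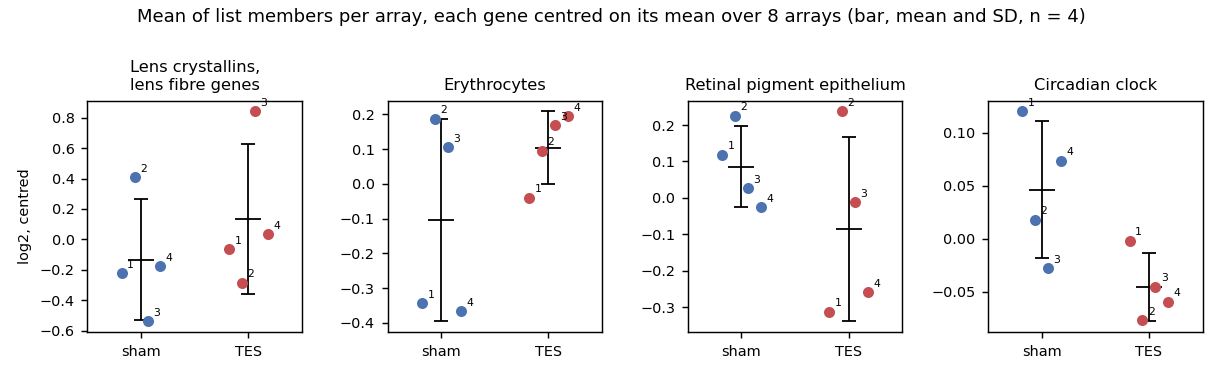
Mean log2 signal of the members of 4 lists on each array, each gene centred on its mean over the 8 arrays, with points numbered by replicate and bars for the mean and SD of 4 arrays per group. The lens list is highest on TES 3 (0.84) and sham 2 (0.41), the erythrocyte list lowest on sham 1 and sham 4 (-0.34 and -0.37), and the pigment epithelium list lowest on TES 1 and TES 4 (-0.31 and -0.26).

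The last comparison asked whether the arrays group by treatment. Arrays of different groups lay 34.4 log2 units apart on average over all genes and arrays of the same group 34.1, a difference of 0.31. An exact one-sided permutation test over 35 splits gave p = 0.286, where the smallest p the design allows is 0.0286. The difference was -0.03 with genes below the median signal left out and -0.02 without TES 4. The first principal component held 22.5% of the variance and the second 17.8%. Sham 2 lay far out on the first and TES 4 on the second.

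**Figure D4:**
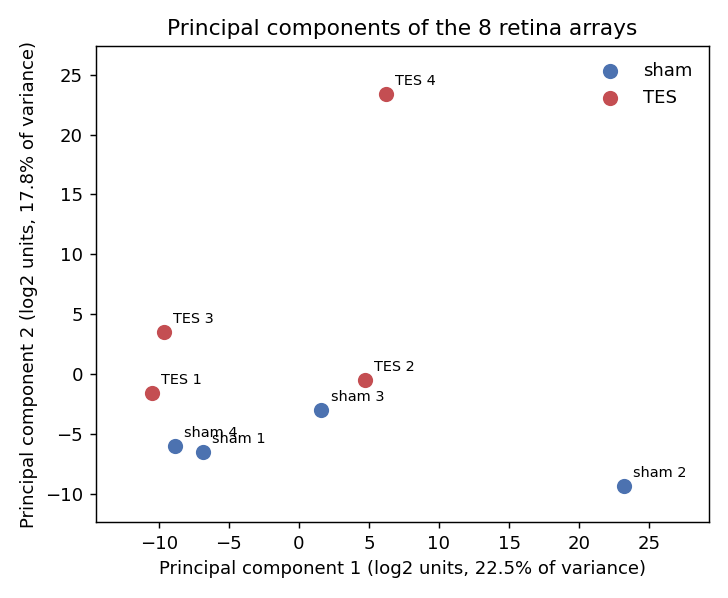
First and second principal components of the 16633 gene values, in log2 units, with sham arrays in blue and TES arrays in red. Sham 2 lies at 23.2 on the first axis and TES 4 at 23.4 on the second, away from the other arrays.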

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

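The tests on the lens and pigment epithelium lists, on the low-signal genes and on the counts of genes over splits were chosen after those results had been seen. The count of gene lists over splits and the quantile test of the split with the most genes were chosen before.

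In each group of 4 arrays, a value was singled out when the highest or lowest array's gap to its neighbour took nearly the whole range of the group. Of 274 groups of values tested, 9 met this, where chance gives about 1 in 20 groups, or 13.7. The values below are that gap as a share of the range. Among genes they were Per1 (0.842, TES 3 lowest at 8.10), Mt1a (0.918, TES 2 highest at 10.22), Rdh5 (0.834, TES 2 highest at 5.31) and Cntf (0.859, TES 4 lowest at 5.61). Among lists they were amacrine cells (0.855, TES 3 highest), the Bcl2 family (0.892, sham 2 highest), hypoxia and glycolysis (0.943, sham 2 lowest) and immediate early genes (0.903, TES 2 lowest). TES 4 had the lowest mean correlation with the other arrays in its group (0.857), 0.991 against 0.992 for the next.

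For the study's thresholds, 9 of the 35 splits of the 8 arrays gave at least the real 597 genes, and the highest other split gave 1072, so chance could not be excluded. Of these genes, 82.1% lay below the median signal, within the 64.0% to 89.0% of the other splits, as noise of low-signal genes would give. For genes and lists past the adjusted p the real count was 0, so that all 35 splits gave as many by construction, which says nothing about chance. Among other splits the highest count of genes was 1, and that of lists, in a different split, was 5.

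The split with 1072 genes set sham 1, sham 4, TES 1 and TES 3 against the remaining arrays, and the next highest gave 667. This points to a structure of the samples that crosses the treatment. Sham 1, sham 4, TES 1 and TES 3 had the highest SDs over genes (2.13 to 2.16, against 2.07 to 2.11 on the remaining arrays). They were also the only arrays with negative values on the first principal component (-6.9 to -10.5, against 1.6 to 23.2). That component comes from the same gene values as the count of genes, so it is not separate support for such a structure. A difference in signal spread between arrays may contribute, since the count was 766 after quantile normalization, which gives every array 1 distribution. It was then still above the 629 of the next split but by less than 1.5 times, so spread and another source cannot be told apart for these arrays. No label gives a batch, and no biological explanation was tested.

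The lens list differed between arrays of the same group. Cryba2 reached 9.93 on TES 3 and 8.84 on sham 2 against 5.003 to 7.927 elsewhere, Cryba1 reached 8.33 and 7.17, and Cryab stood at 6.98 or more on every array. Of the 15 members, 4 lay above the median signal and 1 was on another list. The within-group SD of the list's array means was 0.447, above 100% of 10000 random lists matched on signal (median 0.0512), which restates the spread and does not show its source. The mean of the 6 lens genes that are not crystallins was also above the rest of the group, by 0.33 on sham 2 and 0.54 on TES 3 with 5 of 6 genes higher on each, at or above the 99.15th percentile of random lists. These were also the highest arrays of their groups by the crystallins alone, but 4 of the 6 genes lay at or below the 95th percentile of olfactory receptors. Lens tissue carried over in different amounts may contribute and cannot be told apart from other sources. The test of the list for TES against sham did not pass (camera adjusted p 0.0752).

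The pigment epithelium list also differed between arrays of the same group, with a within-group SD of 0.195, above 100% of random lists (median 0.0397), which again does not show the source. Of the 34 lists, 7 lay above the 95th percentile of 1000 random lists. They were lens, erythrocytes (SD 0.219), pigment epithelium, corneal epithelium (0.116) and, with smaller SDs of 0.059 to 0.072, extracellular matrix, immediate early genes and oxidative phosphorylation. Of its 19 members, 10 lay above the median signal and 1 was on another list, and the abundant Rgr and Ttr were at 8.67 ± 0.26 and 9.05 ± 0.21 after sham and at 8.19 ± 0.44 and 8.58 ± 0.51 after TES. Candidate explanations are epithelium left on the retina in different amounts and a loss of epithelial transcripts on every TES array. The mean of 2 TES arrays (TES 1 and TES 4) lay below the lowest sham array, while TES 2 lay above the sham mean by more than its SD. TES 2 (0.238) was the highest of all 8 arrays, and TES 3 (-0.012) lay within the sham range of -0.025 to 0.225. A lower list mean on every TES array was thus not seen. Differing amounts of epithelium could hide a loss, so these values do not decide. Dissection and treatment cannot be told apart for this list.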

How the results depend on the processing

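Alternatives were fixed beforehand except the joint omission of sham 2 and TES 4, the arrays least correlated with the others in their groups. The count of genes past the adjusted p was 0 under every alternative run, with smallest adjusted p from 0.124 (each probe set alone) to 0.967. The smallest adjusted p was 0.850 without the lowest quartile of signal and 0.967 without genes below the median. In simulations with 4 arrays per group and 200 changed genes, 3.8% of genes changed by 1.2 fold were called. Where no cause is given, the cause was not tested.

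The study's thresholds gave 367 genes without the lowest quartile of signal, 129 without genes below the median and 24 at 1.5 fold, where fewer genes could pass. They gave 927 with no fold minimum and 348 with the unmoderated equal-variance test. Each probe set tested alone gave 10921 of 213067 (5.13%). As many passed the unadjusted p alone, so the fold minimum removed none. The matching share of genes is the 5.57% with no fold minimum. Leaving out 1 array gave 618 to 757, and sham 2 and TES 4 together 678, with 325 of them among the original 597. The median probe set per gene gave 850 genes, of which 335 were among the 597, and the probe set of highest mean gave 805, of which 190 were. The remaining alternatives gave 560 to 678. Same-numbered arrays deviated together with r of 0.124, 0.132, 0.0056 and -0.119. For sham 1 and sham 2 the TES array of the same number was the closest, for sham 3 and sham 4 it was not. A pairing by replicate number is thus neither shown nor excluded. The replicate block gave 678 genes and changed no other call. It brought the camera adjusted p close to the threshold for the erythrocyte list (0.0503 instead of 0.0752) and the pigment epithelium list (0.0503 instead of 0.123). For the lens list that value rose from 0.0752 to 0.125. With an estimated correlation it was 0.925 for all of these lists. With the replicate block, the unadjusted p in limma was 0.020 instead of 0.080 for Egr1 (adjusted p 0.754). For Fos it was 0.097 instead of 0.080 (adjusted p 0.843). 

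Lists past the adjusted p numbered 2 without the lowest quartile (lens, pigment epithelium), 3 without genes below the median (gliosis, cytokines, pigment epithelium), 3 with the probe set of highest mean (erythrocyte, lens, pigment epithelium), 2 with array weights and 2 without sham 2 and TES 4 (erythrocyte, lens each time), and 0 to 3 with 1 array left out. No list passed with an estimated correlation. The separation of the arrays was -0.031 without genes below the median and ran from -0.015 (without TES 4) to 0.596 (without TES 2) with 1 array left out.

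A change of sign was counted as a reversal where the value also moved by at least 1 within-group SD. By less than that, 68 further list values and 9 further gene values changed sign over all alternatives. The reversals came mainly with the choice of probe sets, and none passed an adjusted p. With the median probe set, log2 differences were -0.12 for Gzmc, 0.089 for Aanat, 0.031 for Opn1sw, 0.047 for Rom1, 0.14 for Igf1, 0.29 for Gfap and -0.066 for the antioxidant list. With the probe set of highest mean they were 0.18 for Ghsr, 0.42 for Tmprss9, 0.12 for Lipt1, 0.34 for Ntn5, 0.11 for Slc17a8, 0.52 for Fgfr3, -0.087 for Trpm1, 0.0051 for Lss, 0.038 for Aanat, 0.26 for Vwf, 0.31 for Gabrd, 0.021 for Gabrg3, 0.22 for Hspb1, -0.017 for Egln3, 0.11 for Cxcl12, 0.19 for Cx3cr1, 0.029 for Ndufa8, 0.065 for Rims1 and 0.25 for Tnfrsf1b. With it the lists of astrocytes (0.074), the Bcl2 family (0.039), caspases (0.052), the TNF superfamily (0.058) and voltage-gated channels (0.015) also reversed, and caspases did with median-centred arrays (0.030).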

Other observations

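The test of exon usage described here was chosen before its result was seen.

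Several other genes of the upper signal range differed in mean without passing the correction, named here after their values were seen. Dio2, which encodes the deiodinase that activates thyroid hormone, differed by -0.58 with overlapping groups, and Cdkn1a, a cell cycle inhibitor gene induced by p53, by -0.49. Slc4a1ap differed by 0.46. The limma adjusted p of these genes lay between 0.823 and 0.843. The hemoglobin genes Hba-a2 and Hbb were at 9.46 ± 0.74 and 5.39 ± 0.86 after sham and at 9.90 ± 0.29 and 5.75 ± 0.27 after TES.

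Because the array measures probe sets along the exons, the use of single probe sets relative to the rest of their gene was also tested, with limma's diffSplice over 14845 genes. It called 255 genes by its Simes test and 21 by its F test. Of the 35 splits, 19 gave at least as many genes by the Simes test, the highest other split gave 1216, and chance could not be excluded. The top genes were Baz2b, Ap2a1 and Clec16a, where single probe sets differed from the rest of the gene by -2.51, -2.40 and 2.20 log2 units. These probe sets spread widely between arrays, with SDs after sham and TES of 0.27 and 1.34, 0.86 and 1.18, and 0.56 and 0.61. The TES mean for Ap2a1 (2.485) and the sham mean for Clec16a (2.015) lay below the 95th percentile of olfactory receptor genes (3.10).

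Of single probe sets, 1 of Rnf181 had the smallest p, with 1.78 ± 0.10 after TES and 3.83 ± 0.20 after sham and a limma adjusted p of 0.124 over 213067 probe sets. Its TES mean lay below the median of olfactory receptor genes (2.31), and its sham mean above their 95th percentile (3.10). Among the 40143 probe sets with no gene or several, none passed the adjusted p in limma and 2120 (5.28%) had an unadjusted p under 0.05.

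Gene lists passed camera's threshold in 28 of the 34 other splits of the arrays, though in none for TES against sham. The lens list passed in 13 of them, the pigment epithelium list in 12, oxidative phosphorylation in 7 and rod photoreceptors in 5. For TES against sham, the correlations estimated for these lists were 0.475, 0.352, 0.221 and 0.360, against camera's preset of 0.01. With a preset that low, camera's p-values are too small for such lists. A pass at the preset is therefore weak evidence of a difference, and the other splits were not run with an estimated correlation.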
